A study of Mus musculus with 6 samples.

How the data were processed

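RNA was measured in 6 libraries of cultured mouse spermatogonial stem cells, the germline stem cells of the testis, taken from DBA2 animals at postnatal days 5 to 8. Per the labels' protocols, the cultures received 2 uM EPZ5676 or 0.2% ethanol for 2 weeks, RNA was extracted with TRIzol, and libraries were made with a stranded poly(A) mRNA kit. Each group had 3 libraries, numbered 1 to 3 in the labels, and the series' design text calls them biological triplicates.

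The deposited gene table holds whole-number counts per gene symbol for 24495 symbols, and a second deposited table holds whole-number counts for 53 rows of repeat families. Per the submitters' processing notes, STAR, featureCounts, edgeR, Bowtie and the mm9 build were used, with no versions, roles or settings. The gene annotation, the use of strand and the treatment of reads with several alignments are not given in the sources used here. Column totals of the gene counts ran from 17784332 to 54645903. Repeat totals exceeded the gene total of the same library 2.41 to 3.83 times, so a repeat count cannot be read as a share of the gene reads. The reference tables at hand are on GRCm38.p6 and not on mm9, so no coordinates are given. They served only to match 23622 of the 24495 symbols and to find which genes neighbour each other.

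Counts were analysed as deposited in R 4.3.3. Genes were filtered with filterByExpr, which kept 14855 genes, and 3729 symbols had no count in any library. Library sizes were scaled by TMM, and EPZ5676 was compared with ethanol by edgeR's quasi-likelihood test (edgeR 4.0.16), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-normalised. Means are given with the SD over 3 libraries, and log2 fold changes with their SE. The test design, the 35 gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named Dot1l, Gfra1, Ret, Etv5, Id4, Zbtb16, Kit and Stra8, then the 12 highest and 12 lowest log2 fold changes among called genes with a mean of at least 5 CPM and groups that did not overlap, then up to 4 called members of each list, then up to 10 repeat families by smallest p. Because the fit without pairing called 0 genes, the same rule was also applied to the fit with the replicate number as a block, a decision made after that result was seen. Members that passed only when adjusted over a list alone are named outside the rule, after their values were seen. An item that the rule took is not reported here.

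Whether replicate numbers pair the samples was checked by the correlation, across genes, of each library's deviation from its group mean. Same-numbered libraries correlated at 0.41, 0.61 and 0.34 for replicates 1, 2 and 3. The other combinations lay between -0.49 and 0.28, and each library correlated best with the one that shared its number. All 3 values exceeded 0.1, the bound set for treating the numbers as pairs, so values from the fit with the replicate block stand beside the results they change. EPZ5676 replicate 1 with ethanol replicate 3 (0.278) and EPZ5676 replicate 3 with ethanol replicate 1 (0.149) also exceeded it. Deviations within a group cancel out, so a replicate 2 apart in both groups raises every correlation between replicates 1 and 3. The bound therefore cannot decide pairs 1 and 3. The correlations and the blocked calls were computed in the same run. The pairing is read from the labels' numbers and from the data, since no label states what the numbers stand for. The unblocked fit has 4 residual degrees of freedom and the blocked fit 2. The common biological coefficient of variation was 0.148 without the block and 0.0785 with it.

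Gene lists with at least 3 tested members, 31 of the 35, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and with fry. Adjustment was over the 31 lists. Members were also counted after adjustment over the list alone, with no adjustment across lists. Repeat families with at least 10 counts in at least 3 libraries were tested with the same edgeR test, using the effective library sizes of the gene counts. Of the 53 rows, 3 that name no family held 0.171% to 0.24% of repeat counts per library and were left out, and 2 more fell under the count minimum, leaving 48 families.

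Summed HoxC counts of each pair were compared by an exact (Clopper-Pearson) 95% interval of their ratio, scaled by effective library size. All 15 pairs of libraries, within and between groups, were compared by chi-square over genes with at least 20 counts. The statistic per degree of freedom was 3.64 or more for all 15, so no library was a copy of another within sampling noise. The tests were checked on simulated counts for 14855 genes with the means and library sizes of these libraries, 100 genes changed 1.5-fold and 100 changed 2-fold. Changed genes were drawn from those with a mean of at least 5 CPM, which no HoxC gene reached (Hoxc10, the highest, had 3.12 CPM). Simulated pair effects came from fits with the replicate number as a term, so they take the pairing as given. Without simulated pair effects, the unblocked EPZ5676 against ethanol fit recovered 50% of the 1.5-fold and 88% of the 2-fold changes with 11 false calls, and the blocked fit 40% and 83% with 8. With pair effects, the unblocked fit recovered 30% and 85% with 0 false calls, and the blocked fit 89% and 100% with 12.

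Alternatives were DESeq2 (1.42.0), limma-voom, other scaling factors, other filters, an adjusted p threshold of 0.01, each library left out in turn and the replicate block. After seeing the data, replicate 2 as a batch term, the fit without both replicate 2 libraries, and the same settings within the blocked fit, with DESeq2 also run without its independent filtering, were added. A gene that DESeq2 gave no adjusted p was taken as not called. A pseudocount alternative listed for repeat families was not run, since that table holds counts.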

Results

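The series compared cultured mouse spermatogonial stem cells exposed to EPZ5676 (pinometostat), a small-molecule inhibitor of the histone methyltransferase DOT1L, with cells given its ethanol vehicle. There were 3 EPZ5676 and 3 ethanol libraries. Gene counts totalled 19866337, 54645903 and 20676993 in EPZ5676 replicates 1, 2 and 3, and 19554140, 17784332 and 21046473 in ethanol replicates 1, 2 and 3. Between 18493 and 19887 gene symbols had at least 1 count in a library. The question the design poses is which transcripts and repeat families differ when DOT1L is inhibited for 2 weeks.

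Both replicate 2 libraries stood apart from the others. The first principal component carried 48.7% of the variance and placed EPZ5676 replicate 2 at 25.1 and ethanol replicate 2 at 39.6, while the other 4 libraries lay between -18.0 and -13.5. The second component, with 19.3% of the variance, placed the EPZ5676 libraries between -16.8 and -12.1 and the ethanol libraries between 10.05 and 17.9. Fibroblast markers were higher in the replicate 2 libraries, with a median over 26 genes of 40.8 and 57.7 CPM against 24.8 to 37.9 CPM in the other 4.

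**Figure D1:**
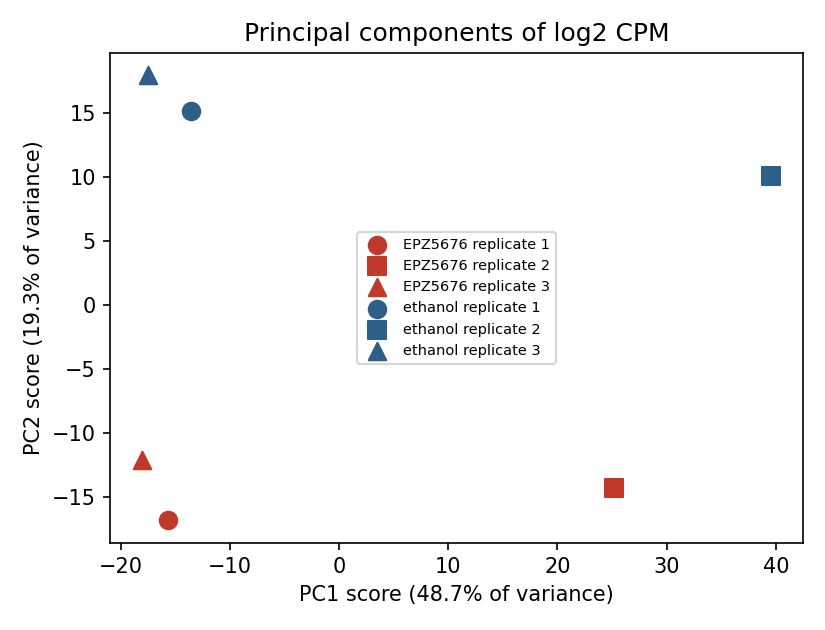
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, coloured by treatment and shaped by replicate number. The replicate 2 libraries lie at 25.1 and 39.6 on the first component, and the second separates EPZ5676 (-16.8 to -12.1) from ethanol (10.05 to 17.9).

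Genes of the HoxC cluster, which encode transcription factors that pattern the body axis, were lower in the cells given EPZ5676. Their summed level was 5.23 ± 0.182 CPM (SD, n = 3) with EPZ5676 and 17.1 ± 4.48 CPM (SD, n = 3) with ethanol, a 3.27-fold difference. Mean CPM was lower with EPZ5676 for all 9 genes of the cluster. Mean Hoxc10 fell from 5.05 ± 1.25 to 1.19 ± 0.107 CPM (SD, n = 3) and Hoxc8 from 1.70 ± 0.219 to 0.361 ± 0.0609 CPM. Hoxc11 fell from 1.15 ± 0.518 to 0.178 ± 0.0498 CPM, with 3, 13 and 3 counts in EPZ5676 replicates 1, 2 and 3. In the fit with the replicate number as a block, Hoxc10, Hoxc8 and Hoxc11 fell 4.10-fold, 4.50-fold and 5.34-fold. Ppfibp2, which encodes a liprin-family scaffold protein, and Slc35f2, a solute carrier gene, fell 2.09-fold and 1.69-fold in that fit, and Nrk, a protein kinase gene, rose 2.48-fold.

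Without the replicate block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14855 genes. At an unadjusted p under 0.05 it gave 570 higher and 531 lower genes, and the smallest adjusted p was 0.18. limma-voom also called 0 genes, with 1122 at an unadjusted p under 0.05, and DESeq2 called 23 higher and 29 lower. With the replicate block, the edgeR test called 48 genes higher and 49 lower, of which 4 and 5 differed at least 2-fold. That fit gave 2751 genes at an unadjusted p under 0.05, 1339 higher and 1412 lower. All 97 called genes differed in the same direction in all 3 replicate pairs, which selection by this fit favours, and 71 had groups that did not overlap. Of all genes tested, 14.9% had groups that did not overlap. Chance gives 10% only if the libraries are interchangeable, and the replicate 2 libraries stood apart, so 10% is not an exact benchmark. Without pair 1 the blocked edgeR fit called 0 genes, with 1169 at an unadjusted p under 0.05, so every call named here was lost. It called 363 higher and 432 lower genes without pair 2, and 486 higher and 275 lower without pair 3, each with 1 residual degree of freedom. With library totals alone as scaling, the blocked fit called 76 genes higher and 117 lower, a share of higher genes of 39.4% against 49.5%.

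Of the called genes named by the rule, 12 rose in the blocked fit outside the fixed lists. Nrk had a log2 fold change of 1.31 ± 0.11 (SE) with an adjusted p of 0.00983 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tmc3, a member of the transmembrane channel-like family, rose from 75.9 ± 25.5 to 131 ± 28.6 CPM (SD, n = 3), and Peg10, a retrotransposon-derived imprinted gene, from 57.4 ± 4.58 to 93.4 ± 12.6 CPM. Pou4f1, a POU-domain transcription factor gene, had a log2 fold change of 0.77 ± 0.09, and Arnt2, a basic helix-loop-helix partner gene, one of 0.81 ± 0.09. The other genes that rose were Adam22, Elmo1, Ptprq, Dnah5, Cntn3, Ptprd and the predicted gene Gm6880, with log2 fold changes between 0.60 and 0.84.

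Outside the fixed lists, 12 named genes fell in the blocked fit. Slc35f2 went from 140 ± 9.46 to 83.1 ± 6.75 CPM (SD, n = 3), with a log2 fold change of -0.75 ± 0.06 (SE) and an adjusted p of 0.00983 in the blocked edgeR quasi-likelihood test. Ppfibp2 had a log2 fold change of -1.06 ± 0.11 and Dlx3, a homeobox gene, one of -0.86 ± 0.13. Icam1, an adhesion molecule gene, went from 45.3 ± 7.15 to 26.4 ± 3.22 CPM, and Cpt1a, which encodes an enzyme of mitochondrial fatty acid import, from 88.0 ± 21.0 to 60.1 ± 8.86 CPM. Fam78a, Mmp9, Psmb8, Ephb4, Pitpnc1, Capn5 and Grhl1 had log2 fold changes between -0.68 and -0.56.

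**Figure D2:**
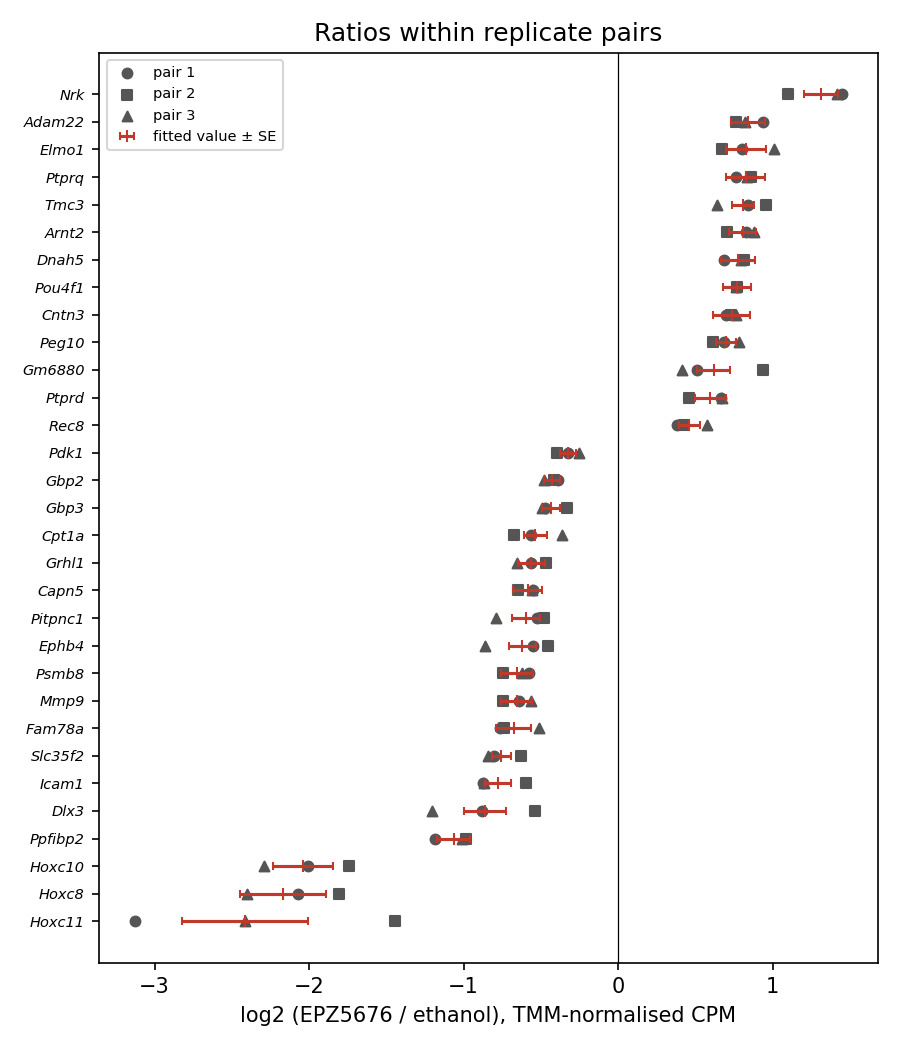
Log2 ratio of EPZ5676 to ethanol CPM within each replicate pair, with 0.05 CPM added (points), and the fitted log2 fold change ± SE of the blocked fit (bars) for genes the naming rule took from that fit. Each gene shown has all 3 pairs on one side of 0, which selection by that fit favours. Fitted values run from -2.42 for Hoxc11 to 1.31 for Nrk.

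The HoxC list had 6 tested members, and Hoxc5, Hoxc6 and Hoxc12 had too few counts to test. The median log2 fold change was -1.89 without the block and -1.82 with it. With the unblocked fit, 0 members passed over all genes and 6 were lower when adjusted over the list alone. With the block, Hoxc8, Hoxc10 and Hoxc11 passed over all genes in the edgeR quasi-likelihood test with adjusted p of 0.0298, 0.011 and 0.0485, and 6 were lower when adjusted over the list alone. Without pair 1, 0 members passed over all genes. In DESeq2 with the block, independent filtering on mean count left all 6 without an adjusted p, so none was called; without that filtering Hoxc8 and Hoxc10 passed and Hoxc11 did not (adjusted p of 0.0184, 3.85e-06 and 0.0529). DESeq2 without the block called these 3, at adjusted p of 0.0051, 3.85e-07 and 0.0355. Camera called the list lower at an adjusted p of 4.85e-13 without the block and 1.95e-07 with it. The call was lost at an adjusted p = 0.525 with an estimated correlation, which was 0.600. With the block it was lost at 0.909, where the estimate of 0.798 rests on 2 residual degrees of freedom. The preset 0.01 takes the 6 members as nearly independent, so the small camera p depends on that setting. fry called it at an adjusted p of 0.0303 without the block, but not with it (0.121). Counts per library were small, from 104 to 431 summed over the cluster, and the exact permutation test of the summed CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow. Hoxc4, Hoxc5 and Hoxc6 transcripts overlap, so their counts can be shared.

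The HoxB list moved in the same direction by less. All 10 members were tested and had negative log2 fold changes, with a median of -0.37. Summed HoxB levels were 207 ± 26.3 CPM with EPZ5676 and 264 ± 10.3 CPM with ethanol (SD, n = 3), a 1.28-fold difference, with an exact permutation p of 0.1. Over all genes, 0 members passed in either fit of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Adjusted over the list alone, 1 was lower without the block, Hoxb9 with a log2 fold change of -0.52 ± 0.11 (SE), and 7 were lower with it. Camera called the list lower at an adjusted p of 5.39e-06 with the preset correlation of 0.01. The call was lost at an adjusted p = 0.625 with an estimated correlation, which was 0.423. Of the other clusters, 2 HoxA genes and 1 HoxD gene had enough counts to test, too few for a test of the list. Hoxd8, the 1 tested HoxD gene, was higher in the blocked edgeR test at an unadjusted p of 0.0436, and did not pass over all genes (adjusted p of 0.258). The HoxA list had enough tested members without EPZ5676 replicate 3, where camera called it higher (median 0.42, adjusted p of 0.0453). It also had enough without ethanol replicate 1, 2 or 3 (medians 0.20, 0.27 and 0.16, adjusted p of 0.798, 0.646 and 0.613) and with no filter, where the direction was lower (-0.18, 0.346), and was not called there. Fibroblast markers, whose values follow with the interferon genes, had a median log2 fold change of -0.21.

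**Figure D3:**
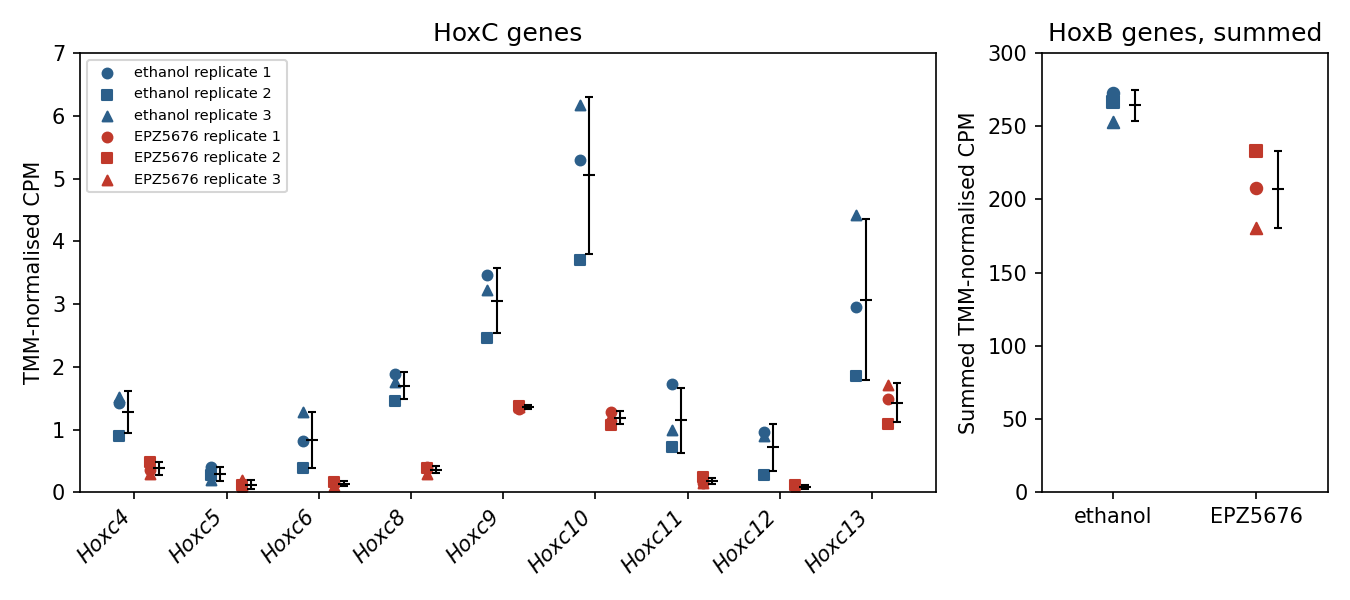
TMM-normalised CPM of the 9 HoxC genes (left) and the summed CPM of the 10 HoxB genes (right) in each library; points are libraries, bars the mean ± SD of 3 libraries. HoxC sums are 5.23 with EPZ5676 and 17.1 with ethanol, and HoxB sums 207 and 264.

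Interferon response genes, which act in antiviral defence, were lower as a list, and Gbp2 and Gbp3, which encode interferon-induced GTPases, fell in the blocked fit. Of 30 tested members, 26 had a negative log2 fold change without the block, and the median was -0.29. Gbp2 went from 185 ± 53.8 to 138 ± 37.6 CPM and Gbp3 from 152 ± 52.0 to 111 ± 32.9 CPM (SD, n = 3). These genes are close paralogs, so reads can be split between them. The list mean was lower in all 3 pairs, with log2 differences of -0.25, -0.15 and -0.31 for pairs 1, 2 and 3. Over all genes, 0 members passed without the block and 2 with it; adjusted over the list alone, 0 passed without the block, and 16 were lower and 1, Ifit2, was higher with it. Camera called the list lower at an adjusted p of 0.000426, and with the block at 3.52e-06. The calls were lost at an adjusted p = 0.625 with an estimated correlation, and at 0.909 with the block. fry called the list in neither fit, at adjusted p of 0.464 without the block and 0.121 with it. Without ethanol replicate 3 the median was -0.19 and the camera call was lost, at an adjusted p of 0.0503; without EPZ5676 replicate 2 the median was -0.20 and the call held, at 0.0401. Fibroblast markers had a median log2 fold change of -0.21, which camera called with the block (adjusted p of 0.00955, lost at an adjusted p = 0.909 with an estimated correlation) and not without it (0.102). With the block, 0 fibroblast markers passed over all genes and 4 (Col1a2, Col3a1, Col5a1 and Sparc) were lower when adjusted over the list alone. Without ethanol replicate 2 the fibroblast median was 0.08, and without EPZ5676 replicate 2 or 3 or ethanol replicate 1 or 3 camera called the list lower, at adjusted p of 0.00846, 0.0405, 0.000291 and 0.0386.

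The G2/M genes, active around cell division, had a median log2 fold change of -0.08, with 40 of 53 negative. WNT target genes had a median of 0.17, with 14 of 16 positive. Camera called these lists at adjusted p of 0.0199 and 0.0497, and the calls were lost at an adjusted p = 0.779 and 0.625 with an estimated correlation. fry called neither, at an adjusted p of 0.410 for both without the block. No member of either list passed, over all genes or adjusted over the list alone, in either edgeR fit. The G2/M call was lost without EPZ5676 replicate 1 or 3 or ethanol replicate 1 or 3, at adjusted p of 0.0918, 0.116, 0.0647 and 0.149, with medians of -0.04, -0.07, -0.08 and -0.07. The WNT call held without EPZ5676 replicate 3 and was lost without any of the other 5 libraries, at adjusted p between 0.0724 and 0.294, without both replicate 2 libraries, at 0.0942, and with a CPM of at least 1 in 3 libraries (0.069) or no filter (0.261).

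None of the 8 genes named in advance passed over all genes. Dot1l, the gene of the inhibitor's target, was at 243 ± 40.4 CPM with EPZ5676 and 202 ± 3.92 CPM with ethanol (SD, n = 3). Gfra1, a GDNF co-receptor of undifferentiated spermatogonia, was at 52.2 ± 7.66 and 69.5 ± 3.30 CPM, with a log2 fold change of -0.41 ± 0.12 (SE), and Ret, its signalling partner, had one of -0.38 ± 0.20. Kit, a receptor of differentiating spermatogonia, had a log2 fold change of -0.37 ± 0.13, and Etv5 one of 0.18 ± 0.08. Id4, Zbtb16 and Stra8 had values of 0.10 ± 0.18, 0.04 ± 0.19 and 0.05 ± 0.23. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of the 8 genes ran from 0.596 to 0.977 without the block, with Dot1l, Gfra1, Etv5 and Kit at an unadjusted p under 0.05. With the block, Kit and Gfra1 had the smallest adjusted p, 0.0586 and 0.0611.

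The median log2 fold change was -0.01 for 27 undifferentiated spermatogonia genes and -0.00173 for 17 differentiating spermatogonia genes. It was -0.06 for 24 meiotic prophase genes, 0.11 for 10 spermatid genes and 0.03 for 23 germline and piRNA pathway genes. Camera called none of these lists. Rec8, a meiotic cohesin gene, rose from 53.05 ± 5.72 to 72.8 ± 3.85 CPM (SD, n = 3). In the blocked fit Rec8 was the only member of these 5 lists to pass over all genes. It was higher without the block when adjusted over the list alone. With the block, 20 of the 35 lists held a member that passed when adjusted over the list alone, against 4 without it. The blocked edgeR test gave 2751 of all 14855 genes an unadjusted p under 0.05, so such members do not mark a list as affected. Adjusted over the list alone with the block, Neurog3 was higher and Gfra1, Cdh1 and Upp1 lower among undifferentiated genes. Sohlh2 and Ctcfl were higher and Kit and Dnmt3b lower among differentiating genes. Rec8, Sycp2 and Meioc were higher among meiotic genes, Tdrd6, Dppa3 and Kdm1b were higher and Mov10l1, Mael and Tex19.1 lower among germline and piRNA pathway genes, and 0 spermatid genes passed. The median and the mean or camera's direction differed in sign for the undifferentiated, differentiating and meiotic lists.

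With all 6 libraries, camera called none of the lists of chromatin, signalling, cell cycle and metabolic genes that follow. Medians were 0.05 for 18 genes of DOT1L and its elongation partners, 0.05 for 14 DNA methylation genes, 0.06 for 27 Polycomb genes, 0.10 for 7 Hox cofactors, 0.09 for 13 pluripotency genes and 0.14 for 16 somatic lineage transcription factors. Medians were -0.04 for ERK feedback and -0.04 for retinoic acid response genes, -0.02 for G1/S genes, -0.09 for p53 targets, -0.02 for senescence genes, -0.02 for cholesterol synthesis, -0.05 for the integrated stress response and -0.08 for glycolysis. Camera called p53 targets lower without EPZ5676 replicate 3 (median -0.10, adjusted p of 0.0453) and glycolysis genes lower without EPZ5676 replicate 1 (median -0.12, adjusted p of 0.039), and neither list in any other fit. The p53 median was -0.01 without EPZ5676 replicate 2 and 0.01 without both replicate 2 libraries, and the glycolysis median was -0.02 without ethanol replicate 1. In the glycolysis list Pdk1, a pyruvate dehydrogenase kinase gene, fell from 351 ± 50.7 to 281 ± 43.6 CPM (SD, n = 3). It was called lower in the blocked fit. Adjusted over the list alone with the block, Mllt1, Kmt2a and Men1 were higher and Aff1 lower among DOT1L partners, Zfp42 and Gdf3 higher among pluripotency genes and Asns higher and Sesn2 lower in the integrated stress response. Spry4 of the ERK feedback list and Cyp26a1 and Tgm2 of the retinoic acid list were lower, as was Eif1a, the 1 tested cleavage-stage gene, whose p was thus unadjusted. None of these members named from adjustment over the list alone passed over all genes in either fit. Signs of median, mean and camera's direction differed for the retinoic acid, senescence and cholesterol lists. Of the mitochondrially encoded transcripts, 0 were tested.

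Camera called none of the other lists of testis cell type markers with all 6 libraries, in either fit. Medians were -0.05 for 13 Sertoli, -0.05 for 4 Leydig, -0.06 for 11 smooth muscle and peritubular, -0.11 for 10 macrophage and -0.08 for 10 endothelial markers. Without EPZ5676 replicate 2 camera called macrophage markers lower (median -0.47, adjusted p of 0.0214). Replication-dependent histones, whose transcripts mostly lack a poly(A) tail, had a median of 0.51 over 13 genes, and -0.77 without EPZ5676 replicate 2. Camera did not call the histones (adjusted p of 0.541), but called them lower without EPZ5676 replicate 2 (0.0401) and higher without EPZ5676 replicate 3 (0.00307). Adjusted over the list alone, Flt1, an endothelial receptor gene, was lower in both fits, and with the block Trf of the Sertoli list was lower and Des, a muscle intermediate filament gene, higher. Over all genes, 0 markers passed in either fit. Signs of median, mean and camera's direction differed for the Sertoli and smooth muscle lists.

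No repeat family passed the test. The edgeR quasi-likelihood test called 0 of 48 families, with 0 at an unadjusted p under 0.05 and a smallest p of 0.103, and with the block also called 0, with 0 at an unadjusted p under 0.05. DESeq2 with the same offsets also called 0, with 0 at an unadjusted p under 0.05. L1 elements, which held 68.8% of repeat counts, had a log2 fold change of -0.06 ± 0.20 (SE), and the endogenous retrovirus family ERVK one of -0.10 ± 0.26. The families with the smallest p were tRNA, with 1972 ± 95.1 CPM relative to gene counts with EPZ5676 and 2316 ± 178 CPM with ethanol (SD, n = 3), hAT?, ERV1?, scRNA, hAT, Charlie, Helitron, MuDR, Y-chromosome and TcMar. Their log2 fold changes lay between -0.24 and 0.68. Ribosomal RNA repeats spread widely within a group, at 1053, 17663 and 161 CPM relative to gene counts in EPZ5676 replicates 1, 2 and 3. L1, ERVK and rRNA were named after their values were seen.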

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

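Replicate 2 as a batch term, the fits without both replicate 2 libraries or without a pair, and the other settings combined with the block were chosen after seeing the data; where a result moved, the cause was not tested. The edgeR calls, 0 with 1101 genes at an unadjusted p under 0.05, stayed at 0 with other scaling, other filters, an adjusted p under 0.01 and each library left out, and limma-voom called 0. DESeq2 called 23 higher and 29 lower (2 and 4 at least 2-fold), the replicate block 48 and 49 (4 and 5), replicate 2 as a batch term 53 and 63 (4 and 6), and the fit without both replicate 2 libraries 6 and 4 (1 and 2). That fit shared 7 calls with the blocked fit, and DESeq2 shared 44.

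Counts in the blocked fit moved with most settings. Higher and lower genes numbered 75 and 88 with DESeq2 size factors, 116 and 151 with upper-quartile factors, 76 and 117 with library totals alone, 242 and 203 with no filter, 14 and 17 with a CPM of at least 1 in 3 libraries, 135 and 158 with DESeq2 (109 and 126 without its independent filtering), 13 and 16 with limma-voom, and 0 and 0 without the block. Leaving out a pair gave 0 to 486 higher and 0 to 432 lower genes. All 97 genes kept their direction in each setting that fitted them, all run on the libraries that selected them. The CPM filter left out 1. Of the 32 genes the rule took from that fit, 32 lost their call without pair 1, 16 with the CPM filter (with Hoxc11, which it left out), 18 with limma-voom and 5 with replicate 2 as a batch term. With DESeq2, 3 lost it, Hoxc8, Hoxc10 and Hoxc11, which its filtering left without an adjusted p as it did 8 of the 97; without that filtering 1 lost it, Hoxc11.

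Camera called 5 lists, 3 to 8 with a library left out, and 6 with the block, which added the fibroblast markers and changed no other list's call. HoxC and HoxB kept direction and call with each other scaling or filter, each library left out, without both replicate 2 libraries and with the block, at the preset correlation. With an estimated correlation both calls were lost, at adjusted p of 0.525 and 0.625 (0.909 for both with the block), and fry did not call HoxB (0.304). Over the 31 lists fry called 1, HoxC, without the block and 0 with it. Camera's direction changed for some uncalled lists, given here with their median log2 fold change. These were Sertoli markers with library totals alone (-0.0628) and retinoic acid response with the CPM filter (-0.0426). With no filter they were Hox cofactors (-0.0343), retinoic acid response (-0.0320), Leydig (0.108) and smooth muscle markers (-0.0526). With the replicate block they were retinoic acid response (-0.0467), senescence (-0.0222) and smooth muscle (-0.148). Without both replicate 2 libraries they were meiotic prophase (-0.0832), Sertoli (0.0952) and histones (-0.186). The median itself changed sign for Hox cofactors and Leydig markers with no filter, and for Sertoli markers and histones without both replicate 2 libraries. The other medians given here kept the sign of the unblocked fit.

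With each library left out, medians ranged from 0.00102 to 0.178 for Hox cofactors, -0.101 to 0.0632 for undifferentiated and -0.0779 to 0.0322 for differentiating spermatogonia, -0.0597 to 0.0199 for meiotic prophase, -0.0582 to 0.0768 for the piRNA pathway, -0.118 to 0.0677 for ERK feedback, -0.101 to 0.0658 for retinoic acid response, -0.10 to 0.152 for senescence, -0.108 to 0.0795 for cholesterol synthesis, -0.165 to 0.0556 for Sertoli, -0.284 to 0.245 for smooth muscle and -0.357 to 0.0833 for fibroblast markers, and -0.765 to 0.834 for histones. Medians changed sign for pluripotency (-0.00723 to 0.209), Polycomb (-0.00523 to 0.0685) and G1/S genes (-0.0608 to 0.00306). The other lists tested with all 6 libraries kept their sign, with medians from -2.30 to -1.73 for HoxC, -0.505 to -0.247 for HoxB, -0.375 to -0.194 for interferon response, -0.101 to -0.0422 for G2/M, 0.122 to 0.196 for WNT targets, -0.105 to -0.0107 for p53 targets, -0.121 to -0.0224 for glycolysis, -0.0597 to -0.00687 for the integrated stress response, 0.0139 to 0.0763 for DNA methylation, 0.0236 to 0.119 for DOT1L partners, 0.0666 to 0.190 for somatic transcription factors, 0.00850 to 0.173 for spermatid genes, -0.104 to -0.00573 for Leydig, -0.472 to -0.0442 for macrophage and -0.175 to -0.00971 for endothelial markers. Log2 fold changes ranged from -0.0496 to 0.244 for Id4, -0.133 to 0.190 for Zbtb16 and -0.148 to 0.341 for Stra8, and the other 5 of the 8 genes kept direction, with 0.159 to 0.392 for Dot1l, -0.613 to -0.252 for Ret, -0.514 to -0.304 for Gfra1, -0.489 to -0.291 for Kit and 0.148 to 0.223 for Etv5. edgeR and DESeq2 called no repeat family in any alternative, with 0 to 4 families at an unadjusted p under 0.05. The pseudocount alternative for repeats was not run, since the table holds counts. With 3 libraries per group, simulated 1.5-fold changes were recovered in 30% to 89% of genes drawn at a mean of at least 5 CPM. Smaller differences, or changes in genes with fewer counts, may go undetected here.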

Other observations

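Apart from the test of splits that part all pairs, every test in this part was chosen after the result it bears on had been seen. Hotair, a noncoding RNA gene in the HoxC cluster, was named after its values were seen. It was at 0.164 ± 0.0725 CPM with EPZ5676 and 0.735 ± 0.292 CPM with ethanol (SD, n = 3), and its adjusted p with the block was 0.0791 in edgeR's quasi-likelihood test. It lies antisense to HoxC genes, and without knowing that counting used strand its reads cannot be separated from theirs.

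Outside structural RNAs and histones, 1354 genes were higher and 1524 lower in replicate 2 than in the other numbers, with treatment as a term. In camera, 5 fixed lists differed. Germline and piRNA pathway genes and interferon response genes were lower in replicate 2, with median log2 differences of -0.17 and -0.26 (adjusted p of 0.0106 and 0.0117). Fibroblast, smooth muscle and retinoic acid response genes were higher, with medians of 0.54, 0.48 and 0.30 (adjusted p of 3.10e-05, 0.00519 and 0.0384). All 5 calls were lost at an adjusted p = 0.828 with an estimated correlation. Nanos2 and Neurog3, genes of undifferentiated spermatogonia, had log2 differences of -1.55 ± 0.20 and -2.50 ± 0.41 (SE), and Krt18, a keratin gene, one of 1.47 ± 0.22. These 3 genes were named after their values were seen.

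Lower HoxC levels with EPZ5676 may reflect the inhibition itself, or fewer fibroblasts, loss of the chromosome region, or counting noise. The 10 most abundant fibroblast markers had a median log2 fold change of -0.30 (range -0.51 to 0.00044). Fn1 and Col1a1 were at 683 and 230 CPM with EPZ5676 and 683 and 267 CPM with ethanol. The 6 tested HoxC genes lay between -2.55 and -1.14. These values argue against a general loss of fibroblasts as the whole cause. They cannot show a loss limited to cells that express HoxC genes, since no library identifies those cells. The 5 tested genes on each side of the cluster had a median of 0.06 (0.0569), with a range of -0.455 to 0.303. The ends of that range were Npff and Nfe2, at a mean of 1.13 and 0.806 CPM. The median argues against loss of the wider region in most cells. It cannot show a loss limited to the cluster or to few cells. The EPZ5676 to ethanol ratio of summed HoxC counts was 0.281, 0.417 and 0.262 in pairs 1, 2 and 3, and its exact 95% interval, which covers counting error only, reached at most 0.501 (0.496 without Hoxc4, Hoxc5 and Hoxc6), which argues against counting noise alone. Whether DOT1L inhibition itself lowers HoxC transcripts was not tested. The libraries used here hold no other DOT1L inhibitor and no measure of histone methylation. For HoxB, list means differed by -0.41, -0.16 and -0.61 in pairs 1, 2 and 3, and fibroblast means by -0.06, -0.47 and 0.01. This argues against a general loss of fibroblasts as the whole cause in pairs 1 and 3 and leaves pair 2 open. Without both replicate 2 libraries the fibroblast median lay 0.437 above the HoxB median (-0.06 against -0.50). The 1-SD bound, 0.263 over 26 markers, is a spread between genes and not an error of that gap. Without ethanol replicate 1 the medians were -0.36 for fibroblast markers and -0.35 for HoxB. With any other library left out the HoxB median was the lower one.

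Lower interferon response genes could follow a loss of fibroblasts. Without both replicate 2 libraries the interferon median was -0.33 and the fibroblast median -0.06, a gap of 0.268 against an SD of 0.263 over the 26 markers. That 1-SD bound was set after the list values were seen, and it is a spread between genes, not an error of the gap. The gap therefore argues only weakly against that loss as the whole cause outside replicate 2. List means in pairs 1, 2 and 3 differed by -0.25, -0.15 and -0.31 for interferon and by -0.06, -0.47 and 0.01 for fibroblast genes. Interferon and fibroblast medians were -0.38 and 0.08 without ethanol replicate 2, -0.29 and -0.10 without EPZ5676 replicate 1, and -0.31 and -0.21 without EPZ5676 replicate 3. The fibroblast median was the lower one without ethanol replicate 1 (-0.30 and -0.36), ethanol replicate 3 (-0.19 and -0.30) or EPZ5676 replicate 2 (-0.20 and -0.31). Over 6 libraries, the 1 relation of its kind computed, the list means had a Pearson r of -0.40 (95% interval -0.915 to 0.607; exact permutation p = 0.439) and a Spearman rho of -0.54 (exact permutation p = 0.297), with r = -0.74 without ethanol replicate 2 and EPZ5676 replicate 1, the 2 farthest from the fibroblast median. Pair 2, where fibroblast genes differed by more than interferon genes, stays open.

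The position of replicate 2 might come from sequencing depth or from more RNA without a poly(A) tail. Ethanol replicate 2, the shallowest library, scored 39.6 on the first component, beyond every library of the other numbers, which argues against depth. Structural RNA took 0.113% to 0.173% of counts in replicate 2 and 0.0224% to 0.0705% elsewhere, yet 2878 genes outside structural RNAs and histones differed, which argues against such RNA as the whole cause. No biological explanation was tested, and what the number 2 shares is not given in the sources used here.

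With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The unblocked fit called 0 genes for the real split and at most 0 for the others, so all 10 gave as many. Of the 4 splits that part all 3 pairs, 1, the real one, gave as many as 97 calls and the highest other gave 0; these too are too few for a share under 0.05.

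A lower NF-kappaB response and lower antigen presentation were considered after Icam1, Nfkbia, Mmp9, Saa3 and Psmb8 had been seen, and these genes were left out of the tests. In the blocked fit camera gave p = 0.00205 for 25 NF-kappaB targets, 23 of them negative, and p = 0.0754 with an estimated correlation. It gave p = 0.00149 for 17 antigen presentation genes, 14 of them negative, and p = 0.0758 with an estimated correlation. Adjusted over the list alone, 0 NF-kappaB targets and 1 antigen presentation gene were lower, and 0 of either list passed over all genes. The estimated correlations were -0.00218 and -0.0517, so the larger p with them does not show that members moved together. The data leave both hypotheses open, and H2 genes share sequence with one another.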
